A study of Rattus norvegicus with 8 samples.

How the data were processed

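RNA from the hippocampus of 8 Sprague Dawley rats was measured on a custom 1-colour Agilent array of the 8x15k format, with 1 array and 1 Cy3-labelled sample per animal. The labels place 5 animals in the early stress group and 3 in the control group, all aged 15 months, and call them biological replicates. Early stress was separation of the pups from the dam for 3 h a day from postnatal day 2 to postnatal day 14. Control litters received routine facility handling, and all litters were weaned at day 30. The labels give no litter for the animals, so litter mates may be present within a group and the p-values treat each animal as independent.

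The deposited table holds 14043 probes and a log2 intensity for each of the 8 arrays. The authors' scanner, background correction and filters are not given in the sources used here. The scale was read from the values themselves: the 75th percentile of every column lay between 0.00 and 0.01, so each array appears to have been shifted to its own 75th percentile, and rows were not centred. The log base is not written in the table. The span of values per array is close to that of a 16 bit scanner only if the base is 2, and differences are therefore given as log2. Flags for detection above background and for saturation were not used here, so a probe near the lowest value of an array has only an upper bound there. The number of arrays, not a read depth, limits the precision.

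The probe IDs of the deposited table are paired with no gene name in the table or in the rat RefSeq gene table at hand (assembly GRCr8), and 0 of the 14043 IDs could be matched. Results are therefore given by probe, and the genes behind the probes are not analysed here. The 40 lists of pathway genes and cell type markers and the candidate genes of stress and plasticity that had been fixed before the data were examined could not be tested for this reason. The rule for naming probes, also fixed before the data were examined, gave the 2 probes with the largest positive and the 2 with the largest negative difference.

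Early stress was compared with control by limma (version 3.58.1 in R 4.3.3), with a linear model per probe over all 8 arrays, no covariate, and moderated variances with a constant prior. All 14043 probes were tested, with no filter on dim probes. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors and 95% confidence intervals of differences come from the moderated variances. Comparisons of a single value per array used a two-sided exact permutation test over the 56 splits of the arrays into 5 and 3, whose smallest possible p is 0.018. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

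The fit was tested on simulated data with the means and moderated variances of the 14043 probes and 200 changed probes, over 20 runs. Normal noise was drawn independently for each probe and array. The rates below therefore hold for that setting and do not cover variation that probes share between arrays. At the adjusted threshold it recovered 55.2% of the probes changed 2-fold and 92.2% of those changed 4-fold. A mean of 8.9 unchanged probes was called per run. Replicate numbers 1 to 3 occur in both groups of the labels. The deviations of same-numbered arrays from their group means correlated at -0.16, 0.14 and -0.10, so the numbers were not taken to pair the animals.

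The alternatives chosen before the data were examined were 3 scalings between arrays, removal of the 25% of probes with the lowest mean, a variance prior with trend, array weights, an unmoderated model, thresholds that include a 1.5-fold difference, each array left out in turn, and the replicate number as a block. A common range for all arrays and removal of probes that were low in control replicate 3 alone were added after seeing the data.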

Results

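Hippocampal RNA of 15-month-old rats was profiled on 8 arrays, 5 from animals separated from their dams as pups (early stress) and 3 from controls that were not separated, with 14043 probes per array. The medians of the arrays lay between -2.54 and -2.29 on the log2 scale on which the 75th percentile of each array is at 0. Early stress replicate 1 spanned -9.93 to 4.84, and control replicate 1 spanned -9.40 to 5.92. Control replicate 3 differed in form at both ends of its range, with 535 probes at its lowest value of -9.43 and 96 at its highest value of 4.94. On the other 7 arrays at most 23 probes lay at the lowest value and 1 at the highest. In control replicate 3, 47 probes lay more than 2 log2 units below every other array, against 3 to 15 on each of the other arrays.

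**Figure D1:**
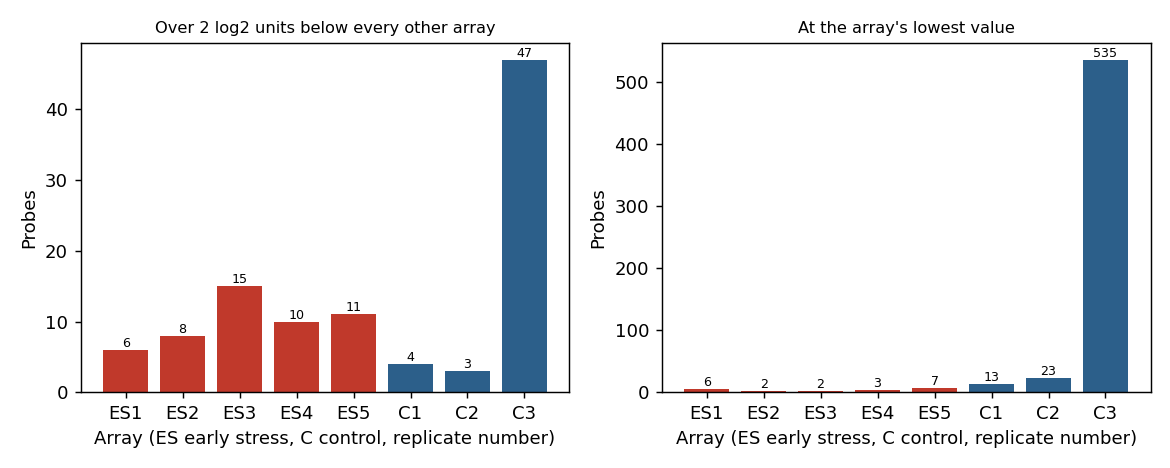
Number of probes (vertical axes) per array (horizontal axes, ES early stress and C control with the replicate number) that lie over 2 log2 units below every other array, left, and that lie at the lowest value of their own array, right. Control replicate 3 has 47 and 535 such probes, against at most 15 and 23 on the other arrays.

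The arrays resembled one another about as much across groups as within them. Pearson correlations across probes ranged from 0.982 to 0.989 over the 13 pairs of arrays within a group and from 0.976 to 0.991 over the 15 pairs between groups. Probes are not independent replicates, so these values only describe similarity. The median SD of a probe between animals was 0.258 (n = 5) in the early stress group and 0.233 (n = 3) in the control group, and the difference of 0.026 had p = 0.768 in an exact permutation test over the 56 splits. A sample SD tends to be smaller with 3 animals than with 5, so no group difference in spread is read from these medians. The first principal component carried 25.5% of the variance, with early stress replicate 1 at -45.5 and control replicate 1 at 43.5 as its ends. Groups differed by -29.1 on this component (early stress minus control, exact permutation p = 0.143), by -27.0 on the second component (p = 0.089, exact) and by -3.8 on the third (p = 0.768, exact). The Benjamini-Hochberg adjusted values over these 3 components were 0.214, 0.214 and 0.768.

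The comparison of early stress with control asks how maternal separation in the first weeks of life is reflected in the hippocampal transcriptome of middle-aged rats. No probe passed the adjusted threshold in limma, and the smallest adjusted p was 0.343. At an unadjusted p under 0.05 there were 1213 probes (8.64% of 14043, against 702 at 5%), of which 839 were higher and 374 lower after early stress. Without control replicate 1 the count at this unadjusted level was 747. The predominance of higher probes depended on the scaling: 69.2% of the probes at this level were higher as deposited, 55.9% after quantile normalization and 53.8% with the medians of the arrays aligned. An unmoderated linear model also gave 0 probes at the adjusted threshold and 1146 at the unadjusted level. Without early stress replicate 5, limma called 2 probes.

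**Figure D2:**
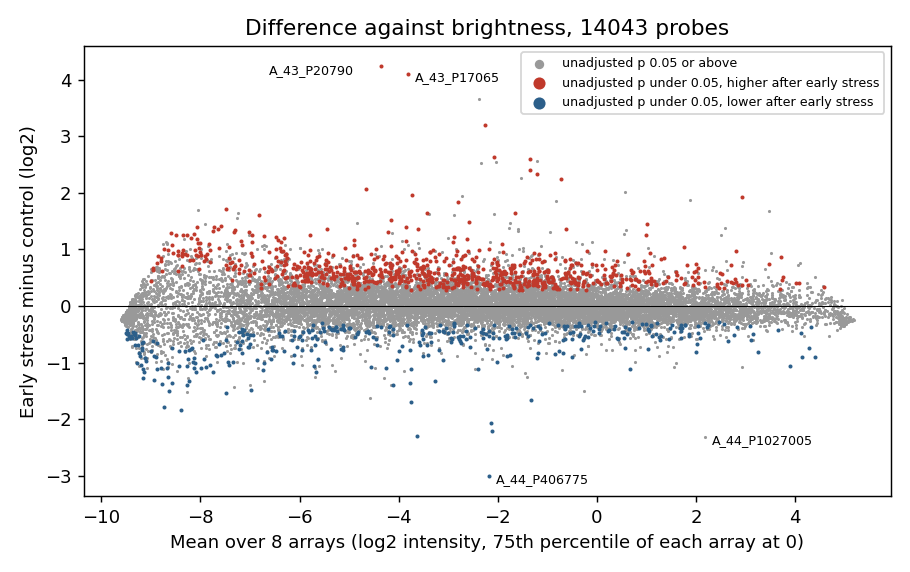
Difference between the early stress and control means (log2, vertical axis) against the mean over the 8 arrays (log2 intensity, horizontal axis), 1 point per probe for 14043 probes, with the 839 higher and 374 lower probes at an unadjusted p under 0.05 in colour. The labelled probes are the 2 with the largest positive (4.24 and 4.11) and the 2 with the largest negative differences (-3.00 and -2.32) in the values as deposited, where control replicate 3 is at the lowest value of its array for A_43_P20790, and no probe passed the adjusted threshold.

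Most differences were small. The median difference over all probes was 0.005 and the SD of the differences was 0.350 on the log2 scale. Differences of at least 2-fold were found for 222 probes, 137 higher and 85 lower after early stress, and 122 of these had an unadjusted p under 0.05. The median half-width of the 95% confidence interval of a difference was 0.44. For 11113 probes (79.1%) the whole interval lay within a 2-fold change in either direction, and for 97.5% it lay within a 4-fold change. All 5 early stress animals lay above all 3 controls for 506 probes and below them for 320. Together these were 826 probes (5.88%), where chance splits give a mean of 3.57%, or 502 probes. Single splits can lie far from such a mean, because probes share variation between arrays. Counts at an unadjusted p under 0.05 ran from 151 to 1763 over the splits. Separated probes were not counted in the other splits, so no excess over chance is read from the 826.

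The probes at an unadjusted p under 0.05 were spread unevenly over brightness. They made up 10.8% of the 2354 probes with a mean between -6 and -4, 8.10% of the 2940 probes between -2 and 0, and 4.10% of the 1343 probes above 2. Control replicate 3 is also limited at its upper end. With all arrays limited to a common range the class above 2 held 35 higher and 27 lower, against 32 and 23 as deposited. In the class from -6 to -4, 195 were higher and 60 lower after early stress. After quantile normalization this class held 166 higher against 116 lower. The median difference over all probes of this class was 0.057 as deposited and -0.013 after quantile normalization. For the class above 2 these medians were -0.075 and -0.021. The direction among the called probes therefore goes with a shift of whole classes that depends on the scaling. Among the 1006 dimmest probes, below -8, there were 39 higher and 64 lower, but these probes lie near the lowest values of the arrays and 516 of them were at the lowest value in control replicate 3. With all arrays limited to a common range the dimmest class held 41 higher and 44 lower, and without control replicate 3 it held 32 higher and 92 lower, so no direction is read from it.

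A_43_P20790 and A_43_P17065 had the largest positive differences in the values as deposited, and neither passed the adjusted threshold. A_43_P20790 averaged -2.76 ± 2.66 (SD, n = 5) after early stress and -7.00 ± 2.15 (SD, n = 3) in controls, with control replicate 3 entered at the lowest value of its array, -9.43. Since that value is only an upper bound, the difference of 4.24 ± 1.51 (SE, adjusted p of 0.529 in limma) for A_43_P20790 depends on the limit of that array, and no fold is given. Without that array the difference for A_43_P20790 was 3.03, with an adjusted p of 0.642 in limma. Early stress replicates 1, 2 and 3 lay at -0.78, -0.88 and -0.98, whereas replicates 4 and 5 lay at -6.53 and -4.63, close to control replicates 1 and 2 at -5.36 and -6.21. A_43_P17065 averaged -2.27 ± 2.10 (SD, n = 5) after early stress and -6.38 ± 0.97 (SD, n = 3) in controls, a difference of 4.11 ± 1.09 (SE) or 17.2-fold, with an adjusted p of 0.476 in limma. Its value of -5.96 in early stress replicate 5 fell inside the control range of -7.25 to -5.34, and the other 4 early stress animals lay between -2.03 and -1.05. Without early stress replicate 5 the difference for A_43_P17065 was 5.03, with an adjusted p of 0.0445 in limma.

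A_44_P406775 and A_44_P1027005 had the largest negative differences, and neither passed the adjusted threshold. A_44_P406775 averaged -3.30 ± 1.38 (SD, n = 5) after early stress and -0.30 ± 0.27 (SD, n = 3) in controls, a difference of -3.00 ± 0.69 (SE) or 8-fold lower, with an adjusted p of 0.470 in limma. All 5 early stress animals, from -4.78 to -1.52, lay below all 3 controls, from -0.59 to -0.07. A_44_P1027005 averaged 1.30 ± 2.72 (SD, n = 5) after early stress and 3.62 ± 0.70 (SD, n = 3) in controls, a difference of -2.32 ± 1.36 (SE) with an adjusted p of 0.63 in limma. Early stress replicate 4 alone was at -3.49, and the other 4 early stress animals lay between 2.01 and 3.30. Without that animal the difference for A_44_P1027005 was -1.12.

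**Figure D3:**
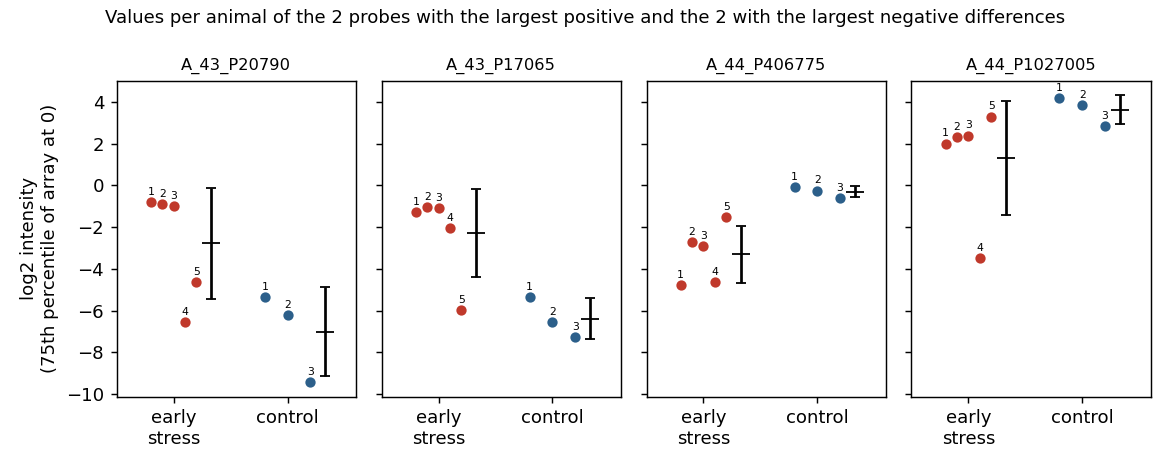
Log2 intensity (vertical axis, 75th percentile of each array at 0) of the 2 probes with the largest positive and the 2 with the largest negative differences in each early stress (n = 5) and control (n = 3) animal, numbered by replicate, with the mean and SD beside each group. Control replicate 3 is at the lowest value of its array for A_43_P20790, early stress replicate 5 lies among the controls for A_43_P17065, and early stress replicate 4 stands apart at -3.49 for A_44_P1027005.

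The 10 probes with the smallest unadjusted p-values comprised 9 that were higher after early stress, by 0.73 to 1.41 on the log2 scale, and 1 that was lower, with a difference of -1.79. Among the 20 smallest, 16 were higher and 4 lower. Ranking by p favours probes with little spread within groups, so the separation of the groups in these probes is no finding of its own. The smallest adjusted p of 0.343 in limma applies to this set as well.

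The 135 probes of the custom design, recognised by their IDs, gave no probe past the adjusted threshold. At an unadjusted p under 0.05 there were 12 of them (8.89%), 9 higher and 3 lower after early stress, and 0 passed in limma when adjusted over these 135 alone. Their mean, relative to the mean of each array, differed by -0.062 between groups (exact permutation p = 0.482). The custom probe with the smallest p averaged -3.88 ± 0.34 (SD, n = 5) after early stress and -5.96 ± 0.92 (SD, n = 3) in controls, a difference of 2.08 ± 0.37 (SE) with an adjusted p of 0.414 in limma. Probes whose IDs begin with A_42, A_43 and A_44 were at an unadjusted p under 0.05 in 6.27%, 8.67% and 9.60% of cases.

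**Figure D4:**
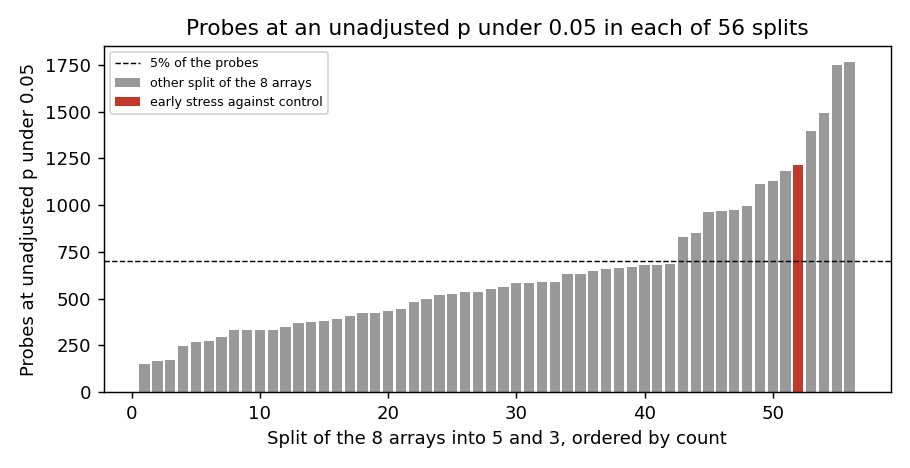
Number of probes at an unadjusted p under 0.05 (vertical axis) for each of the 56 splits of the 8 arrays into 5 and 3 (horizontal axis, ordered by count), with the early stress against control split in red and 5% of the probes (702) as a dashed line. The real split gave 1213 probes, and the highest count of another split was 1763.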

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

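Quantile normalization and leaving out each array were alternatives chosen before the data were examined; their use as tests of the excess described below, the count of splits at the unadjusted level and the tests of control replicate 3 were chosen after the results were seen. In the early stress group, 15 sets of 5 values were checked for a value standing apart from the other 4. Chance flags about 1 in 20 groups that were not selected, and 3 were found. The named probes were chosen for their large differences, which a single extreme animal can produce. The principal components were built from these same arrays. That rate therefore does not apply to them, and the 3 flags are not read as an excess. Early stress replicate 5 scored 34.8 on the third principal component, against -16.1 to -6.6 for the other 4 early stress arrays. A_43_P17065 was at -5.96 in early stress replicate 5, against -2.03 to -1.05 in the other 4. A_44_P1027005 was at -3.49 in early stress replicate 4, against 2.01 to 3.30 in the other 4.

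The 1213 probes at an unadjusted p under 0.05 exceeded the 702 that 5% would give. Splits of the 8 arrays gave a count as large in 5 of 56 cases, the real split included, and the highest other split gave 1763, so chance cannot be excluded for this excess. At the adjusted threshold the real split gave 0 probes and the highest other split gave 7; a count of 0 is reached by all 56 splits by construction, so that count of splits decides nothing about chance. Unequal scaling between arrays is argued against as the whole source of the excess, because quantile normalization left 1303 probes. A single deviating array stays open: the count was 747 without control replicate 1, against 1260 and 1101 without control replicates 2 and 3. Without 1 early stress array it ranged from 936 (replicate 1) to 1401 (replicate 3). Array weights gave control replicate 1 the lowest weight, 0.47, yet the count with them was 1353, so the source is not narrowed to that array. An effect of early stress stays open as well.

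In control replicate 3, 47 probes lay more than 2 log2 units below every other array, with a median drop of 3.23 from the median of the other arrays. On the other 7 arrays the highest such count was 15, so this is more than the scatter of single probes seen there. The lower limit of the values of this array does not account for them, since 3 of the 47 lay within 0.1 of its lowest value. Spots dimmed by a defect of this array and transcripts lower in this animal cannot be told apart: only 3 probes lay as far above all other arrays, but early stress replicates 3 and 4 also had more low than high probes (15 against 1 and 10 against 0), and spot positions were not used here. The 47 probes made up 3 of 2950, 13 of 3877, 31 of 7081 and 0 of 135 probes of the A_42, A_43, A_44 and custom ID series (Fisher's exact test with 100000 resamples, p = 0.0458), and 8 of the 47 had an unadjusted p under 0.05 in the group comparison. Fisher's test takes the probes of this array as independent, which they need not be, so no link with the ID series is read from it.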

How the results depend on the processing

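The count of 0 probes at the adjusted threshold was found under every scaling, filter, prior, weighting, block and added alternative run, and it ranged from 0 to 2 when 1 array was left out, with 2 probes only without early stress replicate 5. A threshold of unadjusted p under 0.05 and at least 1.5-fold instead gave 566 probes, 406 higher and 160 lower. The count at an unadjusted p under 0.05 ranged from 747 without control replicate 1 to 1401 without early stress replicate 3, and stayed within 1.5 times 1213 under all other alternatives but the replicate block. With the replicate number as a block it was 685. The numbers were not taken to pair the animals (1 of the 3 controls correlated best with the early stress array of its own number), but so few arrays cannot decide this. The block leaves early stress replicates 4 and 5 without a partner and so has fewer informative samples. No named probe changed direction in 71 values over 18 alternative fits, and 1 of these values, A_43_P17065 without early stress replicate 5, passed the adjusted threshold. These probes were chosen for the largest differences in the same data. A changed variance prior, an unmoderated model or a probe filter also leaves a difference as it was. The unchanged directions are therefore no independent evidence. The share of higher probes fell to 55.9% and 53.8% under quantile normalization and aligned medians, which moved the median of all probes to -0.017 and -0.057. Control replicate 3 limits the comparison at both ends, where 535 of its probes share its lowest value and 96 its highest. A common range for all arrays gave 1247 probes at the unadjusted level. The alternatives planned for gene lists, candidate genes and several probes of a gene were not run, because no gene names were at hand.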

Other observations

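The tests below were chosen after the result was seen. Some probes fell on 2 clearly separate levels among the 8 animals without dividing them exactly into the early stress and control groups. With a gap of over 1.5 log2 units between at least 2 higher and at least 2 lower arrays, and a highest value above -4, there were 38 such probes, in 20 different patterns of high and low animals. The most common pattern, high in early stress replicates 1 to 3 and low in the other 5 animals, held 8 probes, and the next most common held 4. The 8 probes ranged from -2.26 to 4.38 in the 3 high animals and from -9.43 to 1.47 in the others, with gaps of 1.58 to 3.65, and A_43_P20790 was among them. Only 3 of the 8 had an unadjusted p under 0.05 between early stress and control.

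In 10000 random assignments of the high animals of each probe, the most common pattern held at most 6 probes. The permutation p was 0.0001, the smallest these draws can give. This argues against independent probes for which every animal is equally likely to be high. The draws do not cover animals that tend to be high in many probes, so sharing by independent probes is not decided. The draws treat each probe as a separate transcript, which could not be checked without gene names. Early stress replicates 1, 2 and 3 were each among the high animals in most of the 20 patterns, so sharing of animals was not limited to the most common pattern. One hypothesis is one other tissue in different amounts in these 3 samples. It would order early stress replicates 2 and 3 the same way in all 8 probes. By over 0.5 log2 units, 3 probes were higher in replicate 3 and 1 was higher in replicate 2, with differences (replicate 2 minus replicate 3) from -1.15 to 1.25, and so few probes do not decide it. A litter or an inherited difference shared by the 3 animals may also give such a pattern and was not tested, since the labels give no litter.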
